A study of Mus musculus with 24 samples.

How the data were processed

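The work starts from 2 deposited tables, 1 of counts and 1 of abundances, each with 35727 genes and 24 libraries. The deposited count table holds estimated counts per gene from Salmon, which are not whole numbers and were rounded for the tests. The deposited abundance table holds TPM, scaled by the authors to the same sum in each library. Zeros fell in the same cells of both tables (100%).

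Per the labels, the tissue is inguinal white adipose tissue of male mice aged 18 to 22 weeks on diets with 60% of calories from fat. The series title speaks of mature adipocytes, but the labels' protocols describe no isolation of adipocytes, so the samples are treated as whole tissue. Per the labels' protocols, RNA was extracted with TRIzol and columns with DNase, captured by poly-A and sequenced with paired ends for 200 cycles, at a mean of about 130 M reads per sample. Per the submitters' processing notes, reads were trimmed with fastp 0.23.2 and quantified with Salmon against mm10. The Salmon version, its options and the annotation used are not given in the sources used here, nor is the genetic construct behind the KO. Gene symbols of 34948 genes were matched by name to GENCODE M21 of the same assembly for positions.

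Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 15259 genes holding 99.98% of counts. Differences were tested with edgeR quasi-likelihood F tests (edgeR 4.0.16 in R 4.3.3; TMM scaling; 1 coefficient per group over all 24 libraries; robust fit; 18 residual degrees of freedom). Adjusted p-values are Benjamini-Hochberg over all tested genes with a threshold of 0.05. The interaction is a single F test of whether the genotype effect differs among the 3 diets, and the pairwise differences are contrasts of the same fit. Levels are CPM, computed here from the deposited counts with TMM scaling, given as mean ± SD, and standard errors (SE) of fold changes cover the spread between libraries.

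In all, 50 gene lists were fixed before the data were examined, and those with at least 5 tested members were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01 between genes. The same test with the correlation estimated for each list (statmod 1.5.0) stands beside it. Its p-values are adjusted over the lists. Members were also adjusted over their list alone.

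Named genes follow a rule set before the data were examined. Lpcat3 and Ucp1 are always given. From each comparison come the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out predicted genes and immunoglobulin and T cell receptor segments. From each list that is called or has at least 3 called members come the 3 called members with the smallest p, and from the interaction the 10 smallest p. The text names part of these genes, with the values of some in other comparisons, and says where a gene or ratio was chosen after its values were seen. Some genes that the rule selects are withheld and not reported.

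Alternatives planned before the data were examined were RLE scaling, no filter on low counts (23565 genes), DESeq2 1.42.0, fitting only the groups compared, a block for replicate number, limma on log2 TPM with pseudocounts of 1 and 0.1 and with no filter (23624 genes), the B cell list as a covariate, and leaving out each library. Alternatives added after seeing the data were covariates for the B cell, muscle and gland lists, leaving out the 4 libraries high in B cell markers (mean log2 CPM above 2) or muscle markers (above 4), and leaving out the 100 most abundant genes. Other splits of the libraries were tested in the same way: all 35 for each comparison of 4 against 4, and 60, the real one included, for the average over diets and for the interaction. The latter were drawn at random with a fixed seed, within each diet for the average and within each genotype for the interaction, with 60 chosen to limit run time. Replicate numbers were not treated as pairs, since in no comparison did every pair correlate above 0.1. Partial pairing was not excluded, because for n6 against SFA in KO replicates 1 and 2 correlated at 0.246 and 0.257.

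A self-test put known changes into 200 of 15259 simulated genes with the design of KO against WT on SFA. The pipeline called 60 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 6 of 15059 unchanged genes called. It called 181 of 200 simulated interactions, and camera called 0 of 40 random lists. The simulated genes were drawn independently of each other, so the random lists do not test the assumed correlation between genes. All genes but the 200 had the same mean share of counts in every group. The self-test therefore does not test the scaling for comparisons in which many genes differ.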

Results

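Inguinal white adipose tissue was profiled by bulk RNA-seq in male mice that, per the labels, were wild type (WT) or carried a deletion of LPCAT3 (KO), an enzyme that places fatty acids on phospholipids. The mice ate high-fat diets rich in saturated fat (SFA), omega-6 fat (n6) or omega-3 fat (n3). Each of the 6 groups had 4 libraries, 24 in all, with totals of 43.6 to 62.1 M estimated counts and a median of 50.2 M. Of 35727 genes in the deposited table, 15259 had enough counts to be tested. The p-values of single genes below measure only the spread between these libraries, because the labels do not say whether each came from a separate animal. Those of list tests set the genes of a list against all other genes. With an assumed correlation they do not measure how far a list varies between libraries. Permutation and Fisher exact p-values count genes, not libraries. List tests use an assumed correlation of 0.01 between genes unless an estimated correlation is named. Few list calls held with an estimated correlation: 3, 2 and 2 in the KO against WT comparisons on SFA, n6 and n3.

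Lpcat3, the gene targeted in KO, was read first. Its CPM (counts scaled to library size) in WT libraries were 97.79, 117.5, 129 and 122.8 on SFA, 69.94, 69.35, 72.91 and 66.02 on n6, and 113.7, 113.3, 119 and 111.8 on n3. In KO libraries they were 80.99, 73.81, 76.21 and 70.76 on SFA, 50.05, 47.66, 49.07 and 49.2 on n6, and 58.93, 53.7, 61.33 and 58.98 on n3. Lpcat3 fell with genotype by a log2 fold change of -0.63 on SFA (SE 0.06, adjusted p = 1.88e-08), -0.51 on n6 (SE 0.061, adjusted p = 5.34e-07) and -0.97 on n3 (SE 0.061, adjusted p = 4.71e-11). Lpcat3 transcript therefore remained in KO tissue on every diet. The deposited TPM values of Lpcat3 did not show this fall on SFA (0.07, adjusted p = 0.474) or n6 (0.10, adjusted p = 0.287) and showed a smaller one on n3 (-0.35, adjusted p = 0.000525). The estimated count of Lpcat3 per TPM, relative to the median gene of a library, was 0.809 ± 0.012, 0.794 ± 0.02 and 0.815 ± 0.011 in WT on SFA, n6 and n3 (mean ± SD, n = 4). In KO it was 0.446 ± 0.0058, 0.456 ± 0.029 and 0.454 ± 0.018. The log2 ratio of KO to WT for this quantity, -0.83, was the lowest of 11536 genes compared, with Dock8 next at -0.6. This ratio was looked at after the TPM values of Lpcat3 had been seen.

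**Figure D1:**
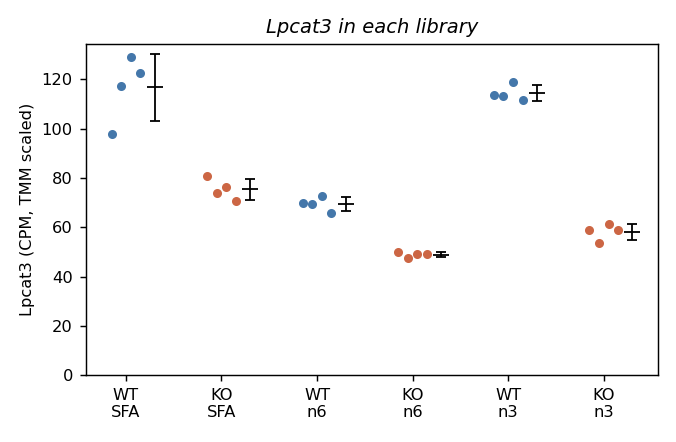
Lpcat3 in each library in CPM (TMM scaled) for the 6 groups of genotype and diet. Points are libraries and bars are the mean ± SD of 4 libraries.

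The KO genotype went with broad differences in expression on every diet. Genes that build fatty acids and cholesterol, such as Acly, Acacb and Fdps, were higher in KO, and so were genes of the mitochondrion such as Dlat and Ndufa10. Cfd (adipsin), which fat cells secrete, and the acute-phase gene Saa3 were lower, together with Cd74 and Lyz2 of antigen-presenting and phagocytic cells. Averaged over the diets, 8795 genes differed between KO and WT (4248 higher, 4547 lower), 490 of them at least 2-fold. Among genes that the naming rule admits, Tmem56 (4.39), Podnl1 (3.58) and Prune2 (3.00) had the largest average rises, in log2 fold change. Saa3 (-3.59), Cfd (-2.67) and Folh1 (-2.41) had the largest average falls. The rule leaves out predicted genes, among them pseudogenes that rose further and are described below. Calls were shared between diets: 1743 genes were higher and 1526 lower in all 3, and 23 were called in all 3 with mixed directions. SFA and n6 shared 2204 higher genes (642.3 expected) and 2261 lower genes (668 expected), with 16 opposite. Expected numbers of shared genes, here and below, assume calls that are independent between comparisons and between genes. SFA and n3 shared 2174 higher (614 expected) and 1767 lower (567.5 expected), with 43 opposite, and n6 and n3 1950 higher (644 expected) and 1760 lower (630.5 expected), with 80 opposite. In TPM units 1387 genes were higher and 9212 lower in this average, with the median of all genes shifted by -0.156, while 5856 genes were called in the same direction in both units.

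On the saturated diet, KO tissue gained the membrane protein gene Tmem56, the matrix gene Podnl1 and the single-strand DNA binding gene Nabp1, and lost Saa3, Nnat and Cfd. Adipsin is made mainly by fat cells, and its transcript was among those that fell furthest. In this comparison 6086 genes changed (3057 higher, 3029 lower), 501 of them at least 2-fold. Tmem56 rose from 1.45 ± 0.575 to 37.4 ± 11.7 CPM (log2 fold change 4.69, adjusted p = 5.21e-10) and Podnl1 from 1.5 ± 0.178 to 27.5 ± 9.71 CPM (4.19, adjusted p = 3.34e-11). Prune2 rose from 45.1 ± 12.2 to 371 ± 47.1 CPM (3.04, adjusted p = 3.15e-12) and Nabp1 from 88.9 ± 28 to 726 ± 77.4 CPM (3.03, adjusted p = 2.54e-10). Hebp2 (2.61) and Xirp2 (2.55, adjusted p = 0.00032) rose too. Saa3 fell from 19.7 ± 2.92 to 1.27 ± 0.285 CPM (-3.95, adjusted p = 6.91e-11), Nnat from 595 ± 86.2 to 58 ± 50.4 CPM (-3.36, adjusted p = 5.47e-07) and Cfd from 1120 ± 189 to 119 ± 48 CPM (-3.24, adjusted p = 1.38e-09). Cyp2f2 (-2.71), Cux2 (-2.62) and Itgad (-2.54) followed. In TPM units the split was 1063 higher and 5419 lower, with the median of all genes shifted by -0.124.

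Among genes that the naming rule admits, Tmem56, Prune2 and Podnl1 led the rises in KO on the omega-6 diet. Cidea, a lipid droplet protein, and Cox8b, a respiratory chain subunit typical of brown fat, rose too. The genes lost included Saa3, Cfd and Folh1. Changed genes numbered 6571 (3206 higher, 3365 lower), 744 of them at least 2-fold. Tmem56 rose to 19.3 from 0.559 CPM (5.14, adjusted p = 9.13e-10), Prune2 to 175 ± 11.5 from 15.8 ± 2.28 CPM (3.47, adjusted p = 5.1e-13) and Podnl1 by 3.41. Hebp2 (3.2), Map7d2 (3.1) and Xirp2 (3.02) completed the largest rises; Xirp2 was uneven in KO (7.16 ± 5.68 CPM), where replicate 1 was high in muscle markers, and rose by 2.64 without the libraries high in B cell or muscle markers. Saa3 dropped to 2.27 ± 0.453 from 43.5 ± 13 CPM (-4.25, adjusted p = 5.32e-12), Folh1 to 3.03 from 27.9 CPM (-3.2, adjusted p = 2.8e-11) and Cfd to 142 ± 25 from 978 ± 218 CPM (-2.78, adjusted p = 7.32e-09). Cyp2f2 (-3.05), Gabrr2 (-2.83) and Hspb7 (-2.59) also fell. Ucp1, the uncoupling protein of brown fat, stayed below 1 CPM in every group; it was called only here among the genotype comparisons (1.85, SE 0.58, adjusted p = 0.0133; SFA -0.61, adjusted p = 0.401; n3 -0.11, adjusted p = 0.886; interaction adjusted p = 0.0987). TPM units gave 1188 higher and 6837 lower genes, with the median of all genes shifted by -0.159.

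On the omega-3 diet the genotype again raised Tmem56, Podnl1 and Prune2 and lowered Saa3, Cux2 and Cfd. Omega-3 fatty acids are carried in part by phospholipids, the products of LPCAT3. Here 5924 genes changed (3065 higher, 2859 lower), 347 at least 2-fold. Tmem56 rose by 3.36 (adjusted p = 2.98e-08), Podnl1 by 3.16, Prune2 by 2.48 (244 ± 23.2 against 43.7 ± 4.58 CPM, adjusted p = 1.08e-10) and Nabp1 by 2.46. Hapln4 (2.21) and Mup19 (2.08) were new to the leading rises. Saa3 (-2.56, adjusted p = 3.24e-08), Cux2 (-2.44), Nnat (-2.01), Cfd (-1.99, 170 ± 28.8 against 678 ± 113 CPM, adjusted p = 8.64e-07), Itgad (-1.96) and Cacna1e (-1.93) fell. With 3 cell-type lists (B cell, muscle and gland) as covariates 3797 genes were called. The gland list did not overlap between genotypes on n3, with mean log2 CPM of -2.96 ± 0.05 in WT and -0.97 ± 0.61 in KO. Here and below, this setting therefore takes out part of any genotype difference on n3, whatever its source. TPM units gave 919 higher and 7504 lower genes, with the median of all genes shifted by -0.187.

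**Figure D2:**
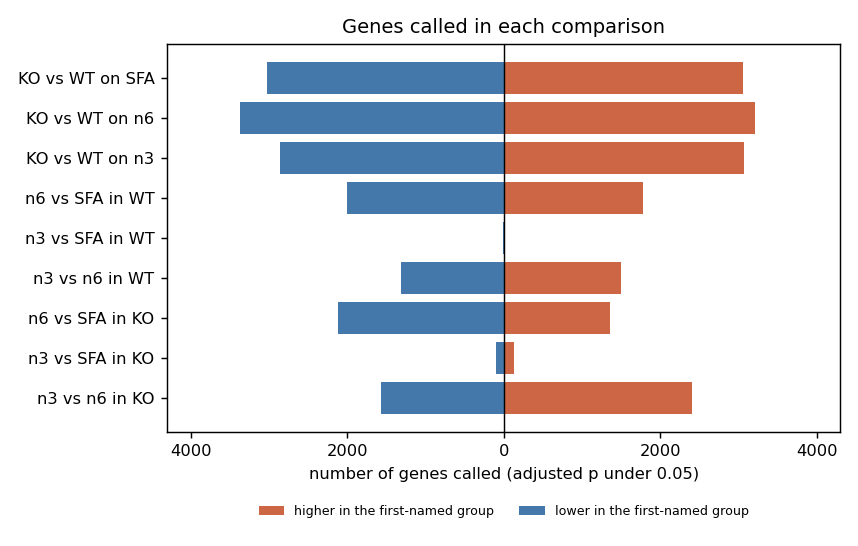
Number of genes higher and lower at adjusted p below 0.05 (edgeR quasi-likelihood) in 9 comparisons of genotype or diet. Bars are counts of genes and each comparison is 4 against 4 libraries.

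Fatty acid synthesis rose as a block. De novo lipogenesis, the pathway from citrate to stored fatty acids, had 16, 16 and 17 of 18 genes higher and none lower in KO on SFA, n6 and n3 (16, 17 and 17 higher adjusted over the list alone). Its median log2 fold changes were 1.09, 1.47 and 1.11 (adjusted p = 2.55e-18, 2.35e-19 and 3.03e-20; adjusted p = 0.0264, 0.0302 and 0.0233 with an estimated correlation). Acacb rose by 1.79 on SFA (adjusted p = 2.48e-13), 2.26 on n6 and 1.54 on n3, and Acly by 1.51 on SFA (adjusted p = 3.67e-14) and 1.15 on n3. Acss2, which makes acetyl-CoA from acetate, rose by 2.37 on n6 (adjusted p = 2.25e-15), where Scd2 rose by 1.75; Me1 rose by 1.47 on SFA and Acaca by 1.32 on n3 (adjusted p = 5.42e-12). Scd1, the desaturase, rose by 0.92, 1.72 and 1.28 on SFA, n6 and n3 (adjusted p = 2.54e-09, 8.76e-14 and 3.16e-11), reaching 99830 CPM in KO on SFA. The rise held in TPM units, with 16, 16 and 16 genes higher.

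Sterol synthesis moved alongside. Of 24 cholesterol synthesis genes, 22, 20 and 21 were higher and 0, 1 and 0 lower in KO on SFA, n6 and n3 (22, 21 and 21 higher and 0, 1 and 0 lower adjusted over the list alone). The medians were 0.98, 1.04 and 0.73 (adjusted p = 2.38e-20, 1.95e-17 and 6.95e-19; adjusted p = 0.0491, 0.0951 and 0.07 with an estimated correlation). Fdps, which makes farnesyl diphosphate, a precursor of sterols, rose by 1.59 on SFA (adjusted p = 3.19e-14), 1.6 on n6 and 1.24 on n3 (adjusted p = 5.42e-12). Lss rose by 1.6 (adjusted p = 2.22e-13) and Sqle by 1.43 on SFA, Nsdhl by 1.57 on n6 (adjusted p = 1.82e-14) and Acat2 by 1.2 on n3. In TPM units 20, 19 and 18 genes were higher and 1, 1 and 1 lower.

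Genes that elongate and desaturate polyunsaturated fatty acids also rose: of 9, 7, 6 and 7 were higher and 2, 1 and 1 lower on SFA, n6 and n3 (7, 7 and 7 higher and 2, 1 and 1 lower adjusted over the list alone). Medians were 0.4, 0.37 and 0.33 (adjusted p = 0.000156, 0.000292 and 0.000136; adjusted p = 0.0264, 0.0405 and 0.0233 with an estimated correlation). In TPM units 5, 5 and 4 were higher and 2, 1 and 2 lower, with medians of 0.23, 0.16 and 0.1. Tecr rose by 1.16 (adjusted p = 2.52e-13), 1.34 and 0.98, Hsd17b12 by 1.25, 1.46 and 1.07, and Fads2 by 1.32 on SFA (adjusted p = 5.78e-11). Of 18 triglyceride synthesis genes, 10, 11 and 11 were higher and 3, 1 and 0 lower (10, 11 and 12 higher and 4, 1 and 1 lower adjusted over the list alone), with medians of 0.33, 0.38 and 0.31 (adjusted p = 0.00649, 7.33e-05 and 4.22e-05; adjusted p = 0.466, 0.352 and 0.279 with an estimated correlation). Agpat2, which makes phosphatidic acid, rose by 1.12 (adjusted p = 7.62e-11), 1.64 (adjusted p = 1.07e-13) and 1 (adjusted p = 1.04e-09); Plin2 rose by 0.97 (adjusted p = 3.13e-10) and Gpam by 0.61 on SFA. In TPM units the triglyceride split was 8 higher and 6 lower, 10 and 5, and 7 and 3.

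Oxidative genes rose with the synthetic ones. Of 27 beta-oxidation genes, 19, 23 and 22 were higher and 1, 2 and 1 lower in KO on SFA, n6 and n3 (20, 23 and 22 higher adjusted over the list alone). Medians were 0.3, 0.54 and 0.48 (adjusted p = 5.74e-08, 1.12e-12 and 3.61e-12; adjusted p = 0.366, 0.232 and 0.209 with an estimated correlation). In TPM units 15, 20 and 17 beta-oxidation genes were higher and 3, 2 and 2 lower, with medians of 0.14, 0.33 and 0.23. Hadha, of the mitochondrial trifunctional protein, rose by 0.65 (adjusted p = 1.07e-09), 0.73 and 0.62. Oxidative phosphorylation had 38, 42 and 43 of 43 nuclear genes higher and none lower (42, 43 and 43 adjusted over the list alone), with medians of 0.26, 0.4 and 0.46 (adjusted p = 7.99e-13, 1.25e-20 and 2.43e-27; adjusted p = 0.435, 0.32 and 0.209 with an estimated correlation). Ndufa10 of complex I rose by 0.51 (adjusted p = 4.53e-08), 0.65 and 0.59 and Ndufs1 by 0.41, 0.53 and 0.45. In TPM units 23, 39 and 41 of these genes were higher and 1, 0 and 0 lower.

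The tricarboxylic acid cycle, which feeds the chain, had 16, 17 and 17 of 17 genes higher (17, 17 and 17 adjusted over the list alone), with medians of 0.36, 0.51 and 0.49 (adjusted p = 2.83e-11, 5.68e-15 and 4.8e-17; adjusted p = 0.366, 0.206 and 0.209 with an estimated correlation). Dlat rose by 0.87 (adjusted p = 1.55e-11), 1.05 and 0.81, Cs by 0.83, 0.89 and 0.75, and Pcx by 0.79, 1.1 and 0.78. Of the 13 mitochondrially encoded genes, 10, 13 and 10 were higher (11, 13 and 11 adjusted over the list alone), with medians of 0.64, 1.02 and 0.66 (adjusted p = 2.38e-07, 4.04e-11 and 2.24e-08; adjusted p = 0.366, 0.206 and 0.209 with an estimated correlation). mt-Nd2 rose by 0.94 (adjusted p = 2.63e-10), 1.37 and 0.88 and mt-Nd1 by 0.79, 1.03 and 0.74. Thermogenic genes followed, with 12, 14 and 13 of 22 higher and 2, 1 and 0 lower (14, 14 and 13 higher adjusted over the list alone) and medians of 0.42, 0.76 and 0.66 (adjusted p = 0.00228, 2.45e-05 and 4.4e-05; adjusted p = 0.366, 0.206 and 0.209 with an estimated correlation). In TPM units the thermogenic medians were 0.21, 0.32 and 0.3 and those of the tricarboxylic acid cycle 0.2, 0.32 and 0.23. Pank1 rose by 0.9 (adjusted p = 6.98e-10), 1 and 0.87, Cpt1b by 1.29 on SFA, Cidea by 2.54 on n6 (adjusted p = 5.47e-09) and Cox8b by 2.02 on n6 (adjusted p = 1.21e-08) and 1.51 on n3.

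**Figure D3:**
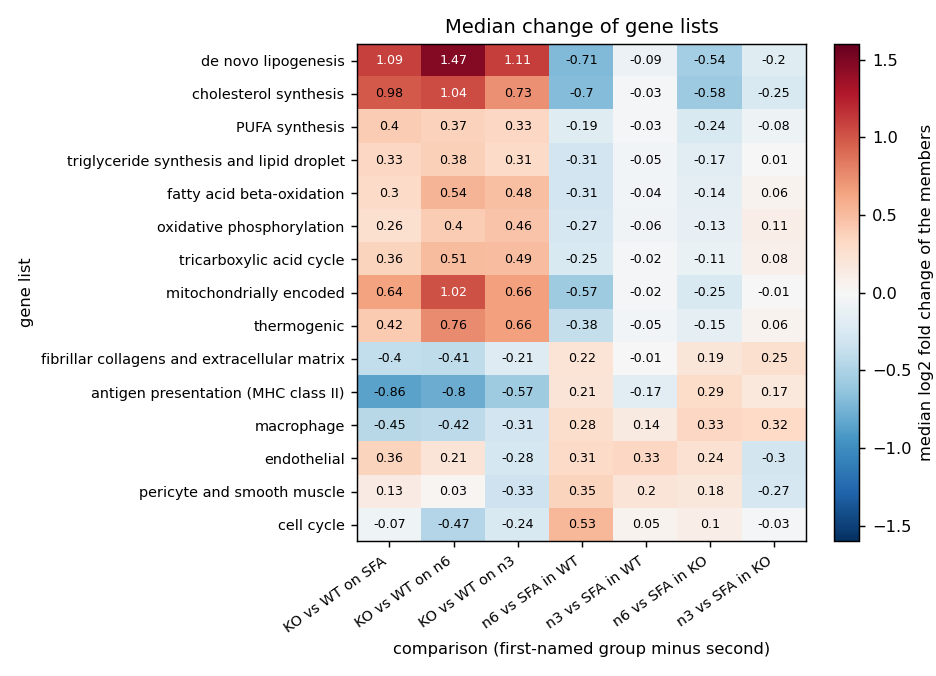
Median log2 fold change of 15 gene lists (vertical) in 7 comparisons (horizontal), printed in each cell and coloured by size. Medians carry no error bars; in TPM units the sign turns for pericyte markers in KO against WT on n6, for the thermogenic, oxidative phosphorylation and tricarboxylic acid cycle lists on n6 against SFA in KO, for triglyceride synthesis on n3 against SFA in KO, and, on n3 against SFA in WT, for the lipid and mitochondrial lists other than lipogenesis and oxidative phosphorylation and for the matrix list.

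Genes of antigen presentation, macrophages and the matrix were lower in KO. MHC class II genes, which present antigen, had 0, 1 and 0 of 10 higher and 7, 7 and 7 lower on SFA, n6 and n3 (the same adjusted over the list alone), with medians of -0.86, -0.8 and -0.57 (adjusted p = 3.47e-05, 0.00119 and 0.00165; adjusted p = 0.366, 0.367 and 0.416 with an estimated correlation). Cd74 fell, at -0.91 (adjusted p = 1.04e-06), -0.89 and -0.58 (adjusted p = 0.000297), and H2-DMb1 at -0.99 (adjusted p = 1.46e-07), -1.09 and -0.77. Of 15 macrophage markers 13, 11 and 7 were lower and none higher (13, 11 and 8 adjusted over the list alone), with medians of -0.45, -0.42 and -0.31 (adjusted p = 0.000145, 0.00131 and 0.00522; adjusted p = 0.446, 0.456 and 0.573 with an estimated correlation). Lyz2, the lysozyme of macrophages, fell at -0.72 (adjusted p = 6.03e-05), -0.81 (adjusted p = 1.14e-05) and -0.42 (adjusted p = 0.00825), Cd14 at -0.6 on SFA and Itgam at -0.8 on n6. With 3 cell-type lists as covariates no macrophage marker was called on n3 (median -0.21), while in TPM units 12 were lower (median -0.5).

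Collagens and other matrix genes had 1, 2 and 0 of 24 higher and 19, 18 and 9 lower (19, 19 and 9 lower adjusted over the list alone), with medians of -0.4, -0.41 and -0.21 (adjusted p = 3.02e-06, 2.45e-05 and 0.00256; adjusted p = 0.366, 0.367 and 0.512 with an estimated correlation). In TPM units 20, 20 and 18 were lower, with medians of -0.57, -0.61 and -0.44. Sparc, which binds collagen, fell at -0.37 (adjusted p = 4.68e-07), -0.42 and -0.29; Col5a2 fell at -0.45 on SFA, Col6a1 at -0.91 and Col6a2 at -0.73 on n6, and Thbs1 at -0.78 on n3. Immediate early genes fell as well, with 9, 8 and 11 of 19 lower (9, 8 and 12 adjusted over the list alone) and medians of -0.26, -0.22 and -0.28 (adjusted p = 0.0186, 0.00493 and 0.000375; adjusted p = 0.37, 0.32 and 0.209 with an estimated correlation). Nr4a2, a rapid-response nuclear receptor, was lower at -0.64, -0.62 and -0.73, Jun at -0.35 on SFA and Atf3 at -1.16 on n6 (adjusted p = 9.41e-06).

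Other lists were called on some of the diets. Cell cycle genes, which serve DNA replication, had 3, 18 and 4 of 22 lower (2, 19 and 1 adjusted over the list alone), with medians of -0.07, -0.47 and -0.24 (adjusted p = 0.192, 5.22e-06 and 0.0121; adjusted p = 0.367 on n6 and 0.585 on n3 with an estimated correlation). In TPM units 6, 20 and 14 were lower (medians -0.17, -0.56 and -0.38), and with 3 cell-type lists as covariates 1 was called lower on n3 (median -0.09). E2f1 fell at -0.65 on n6 (adjusted p = 2.24e-08) and Pcna at -0.41. Ribosomal protein genes had 20, 24 and 1 of 26 lower and 1, 0 and 0 higher (22, 25 and 0 lower adjusted over the list alone), with medians of -0.16, -0.17 and 0.02 (adjusted p = 4.85e-06, 4.96e-07 and 0.617; adjusted p = 0.458 on SFA and 0.414 on n6 with an estimated correlation); in TPM units the n3 median turned to -0.21 with 26 lower. Rps4x fell at -0.24 on SFA (adjusted p = 1.53e-05) and -0.27 on n6. Adipokines and other secreted products split, with 5, 6 and 4 of 18 higher and 10, 10 and 8 lower (5, 6 and 4 higher and 10, 11 and 9 lower adjusted over the list alone), and only SFA was called (median -0.42, adjusted p = 0.0381; adjusted p = 0.366 with an estimated correlation). Rbp4, the retinol carrier, rose by 1.2 (adjusted p = 7.95e-11), 1.26 and 1.14, whereas leptin (Lep) fell at -0.96 on n6 (adjusted p = 9.19e-10). Adiponectin (Adipoq) was at 2021 against 1360 CPM in WT and KO on SFA, 1783 against 1515 on n6 and 1962 against 1649 on n3.

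Vessel markers were called in either direction. Of 14 endothelial markers, 11, 2 and 0 were higher and 0, 0 and 6 lower in KO on SFA, n6 and n3 (the same adjusted over the list alone), with medians of 0.36, 0.21 and -0.28 (adjusted p = 0.00305, 0.0563 and 0.00522; adjusted p = 0.564, 0.702 and 0.582 with an estimated correlation). Kdr, the VEGF receptor, rose by 0.53 on SFA (adjusted p = 0.00346), and Vwf (-0.41, adjusted p = 0.00593) and Tek (-0.32) fell on n3. With 3 cell-type lists as covariates 0 endothelial and 2 pericyte markers were called lower on n3, with medians of -0.19 and -0.31; in TPM units 13 endothelial and 10 pericyte markers were lower on n3, with medians of -0.5 and -0.51. None of the 11 SFA rises was called in TPM units (median 0.18) and 1 was called without the libraries high in B cell or muscle markers. Pericyte and smooth muscle markers had 3, 3 and 0 of 13 higher and 1, 2 and 7 lower, and only n3 was called (median -0.33, adjusted p = 0.00726; adjusted p = 0.488 with an estimated correlation; 1 higher and 8 lower adjusted over the list alone). Acta2 fell on each diet, at -1.17 (adjusted p = 1.38e-08), -1.16 and -0.9.

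Markers of cells that vary with dissection were uneven between libraries. The mean log2 CPM of 14 B cell markers was 2.85 in replicate 3 of WT on SFA, 2.34 in replicate 2 of KO on SFA and 2.97 in replicate 2 of KO on n6; skeletal muscle markers reached 4.5 in replicate 1 of KO on n6. On n6, 8 B cell markers were called higher and 1, Ighm (-0.94), lower (11 and 1 adjusted over the list alone), against 1 and 1 in TPM units and 5 and 1 without those 4 libraries; the list itself was not called (adjusted p = 0.142). T and NK cell markers had 13 of 19 higher and 1 lower on n6 (median 0.86, adjusted p = 0.0136, and adjusted p = 0.544 with an estimated correlation). Without those 4 libraries 3 were called higher and 1 lower (median 0.65). Trac rose on each diet, by 1.79, 2.02 and 1.52. The T and NK cell list as a whole did not, with medians of -0.25 on SFA (1 higher, 2 lower) and -0.26 on n3 (1 higher, 3 lower). Mammary and gland markers had 6 of 10 higher on n3 (7 adjusted over the list alone; median 2.85, adjusted p = 0.0461; adjusted p = 0.585 with an estimated correlation), led by Krt8 (6.64, adjusted p = 0.00404), Ltf (4.69) and Krt18 (2.99), which were at 0.683, 0.516 and 0.883 CPM in KO. In TPM units 2 gland markers were higher on n3 (median 0.38). With 3 cell-type lists as covariates 1 was called (median 0.27), which tests nothing, since the gland list is among those covariates. Hemoglobin and other erythroid markers had 5 of 7 higher on n6 (6 adjusted over the list alone; median 0.48, adjusted p = 0.00867; adjusted p = 0.456 with an estimated correlation), among them Hba-a2 (0.46, adjusted p = 0.000753).

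The effect of genotype was called as dependent on diet for a subset of genes, among them Acss2, Ighm, Map1a and Insig1. Splits of the libraries, given below, left open whether chance can be excluded for their number. Acss2 makes acetyl-CoA from acetate, Ighm is the heavy chain of IgM, and Insig1 holds sterol sensors in the endoplasmic reticulum. The interaction was called for 983 genes, with 3916 at unadjusted p below 0.05. Leaving out single libraries moved this count between 515 (without replicate 3 of WT on n3) and 2527 (without replicate 4 of KO on n3), and 3 cell-type lists as covariates left 87. Acss2 (adjusted p = 2.61e-05) went from 363 to 980 CPM between WT and KO on SFA, 117 to 604 on n6 and 328 to 788 on n3. Scd1 (adjusted p = 0.00178) went from 52750 to 99830, 20630 to 67850 and 31410 to 76440 CPM, and Insig1 (adjusted p = 0.000501) from 608 to 1226, 247 to 861 and 613 to 1125 CPM. Map1a (adjusted p = 0.000118), Pdgfd (adjusted p = 0.000693), Asf1b (adjusted p = 0.000832), Ptger3 (adjusted p = 0.00176) and Sardh (adjusted p = 0.00185) were also among the 10 smallest p-values. Between pairs of diets the genotype effect differed in 137 genes for n6 minus SFA (71 higher, 66 lower), 125 for n3 minus SFA (39 higher, 86 lower) and 1389 for n3 minus n6 (684 higher, 705 lower).

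**Figure D4:**
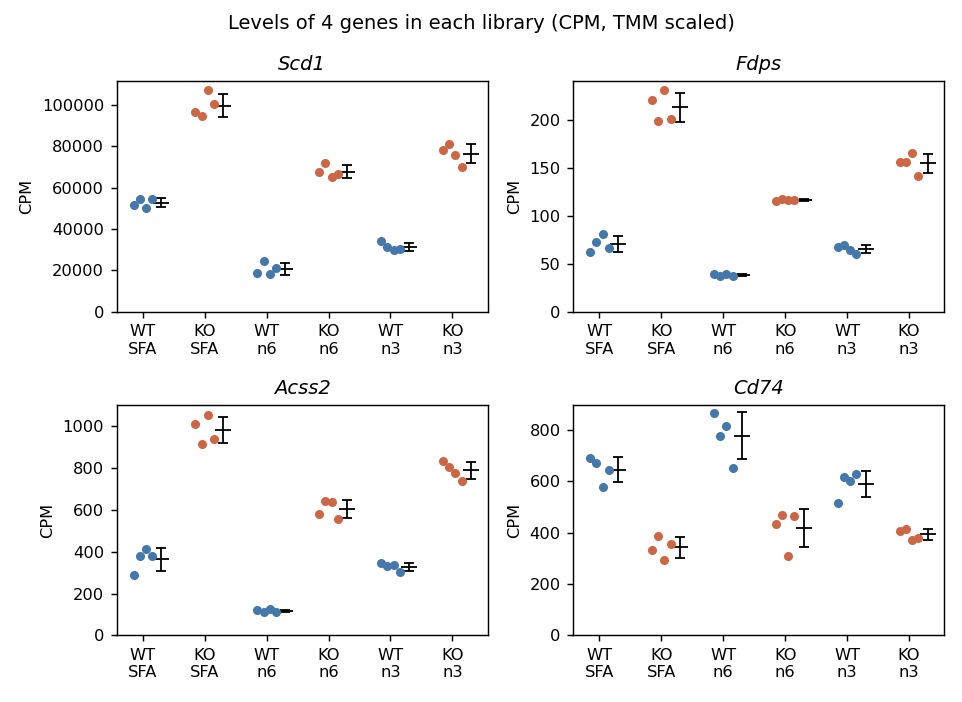
Scd1, Fdps, Acss2 and Cd74 in CPM (TMM scaled) for the 6 groups of genotype and diet. Points are libraries and bars are the mean ± SD of 4 libraries.

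In WT mice, genes of lipid synthesis were lower on omega-6 than on saturated fat. Acss2, Scd2 and Elovl6, which make and lengthen fatty acids, fell, while the acute-phase genes Saa3 and Ptx3 rose. In this comparison 3776 genes changed (1777 higher, 1999 lower; 2393 without replicate 4 of WT on SFA). Acss2 fell from 363 ± 53.2 to 117 ± 6.38 CPM (-1.63, adjusted p = 9.22e-12), with Cck (-2.28, adjusted p = 0.00171), H2-Q10 (-1.76, adjusted p = 4.29e-09), Podnl1 (-1.7), Hephl1 (-1.68) and Tmem132b (-1.6, adjusted p = 0.0252). Hif3a (1.55, adjusted p = 0.00269), Hspb7 (1.49, adjusted p = 0.000309), Ptx3 (1.46, adjusted p = 3.32e-05), Ass1 (1.31, adjusted p = 9.31e-08) and Saa3 (1.15, adjusted p = 0.000192) rose. Lpcat3 itself fell at -0.75 (adjusted p = 1.25e-08). In TPM units 5636 genes were higher and 530 lower, with the median of all genes shifted by 0.14.

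On n6 against SFA in WT, 21 of 24 cholesterol synthesis genes were lower (21 adjusted over the list alone; median -0.7, adjusted p = 1.15e-21; adjusted p = 0.0387 with an estimated correlation), led by Insig1 (-1.3) and Fdps (-0.88). De novo lipogenesis had 15 of 18 lower (15 adjusted over the list alone; median -0.71, adjusted p = 2.44e-21; adjusted p = 0.00982 with an estimated correlation), with Scd2 (-1.25, adjusted p = 2.42e-11) and Elovl6 (-1.24). Polyunsaturated fatty acid synthesis had 5 of 9 lower (median -0.19, adjusted p = 1.01e-05; adjusted p = 0.00982 with an estimated correlation), with Tecr at -0.78. All 43 oxidative phosphorylation genes were lower (median -0.27, adjusted p = 1.15e-21, and adjusted p = 0.215 with an estimated correlation), against 21 in TPM units. Beta-oxidation had 22 of 27 genes lower (median -0.31, adjusted p = 2.67e-12, and adjusted p = 0.2 with an estimated correlation), against 12 lower and 1 higher in TPM units (median -0.13). Mature adipocyte genes had 12 of 24 lower and 1 higher (median -0.25). Matrix genes had 9 of 24 higher and 0 lower (median 0.22), and endothelial markers 5 of 14 higher and 0 lower (median 0.31). Cell cycle genes rose, 19 of 22 (20 adjusted over the list alone; median 0.53, adjusted p = 1.23e-10; adjusted p = 0.207 with an estimated correlation), among them Mcm5 (0.51). Macrophage markers had 6 of 15 higher (median 0.28, adjusted p = 0.000311; adjusted p = 0.408 with an estimated correlation) and inflammatory cytokines 5 of 19 (median 0.19, adjusted p = 0.00722; adjusted p = 0.327 with an estimated correlation), with Ccl2 at 0.87 (adjusted p = 3.61e-05).

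Few genes were called between omega-3 and saturated fat in WT mice. The desaturases Scd1 and Scd2, which put the first double bond into saturated acids, fell, and the hemoglobin genes Hba-a1 and Hba-a2 rose. Only 22 genes were called by edgeR (13 higher, 9 lower), with 2238 at unadjusted p below 0.05; DESeq2 called 339 (155 higher, 184 lower). Removing single libraries moved the count between 1, without replicate 2 of WT on SFA, and 111, without replicate 1. Scd1 fell from 52800 ± 2100 to 31400 ± 1880 CPM (-0.75, adjusted p = 2.5e-05) and Scd2 from 1710 to 1340 CPM (-0.35, adjusted p = 0.0201). Apoc1 (-0.64, adjusted p = 0.012), Wfdc21 (-0.57, adjusted p = 0.012), Pm20d1 (-0.45) and Orm1 (-0.4, adjusted p = 0.0248) fell too. Slit2 (0.57, adjusted p = 0.0322), Hba-a2 (0.56, adjusted p = 0.0165), Hba-a1 (0.52), Cyp4b1 (0.49, adjusted p = 0.0157), Plod2 (0.44) and Sorbs2 (0.4) rose. Lpcat3 was at -0.03 (adjusted p = 0.865).

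Between the omega-3 and omega-6 diets in WT mice, genes of lipid synthesis were higher on omega-3. Elovl3, which elongates fatty acids in fat, and Cck rose, and Saa3, Ptx3 and Hspb7 fell. Here 2813 genes changed (1499 higher, 1314 lower), against 577 higher and 3324 lower in TPM units, where the median of all genes shifted by -0.0942. Tmem132b (3), Cck (2.65, adjusted p = 0.000527), Tmem56 (2.36) and Elovl3 (1.88, adjusted p = 0.00035) led the rises. Hspb7 (-2.22, adjusted p = 5.24e-06), Ptx3 (-1.81, adjusted p = 2.48e-06), Saa3 (-1.63, adjusted p = 4.21e-06), F7 (-1.36) and Hif3a (-1.33) led the falls. Lpcat3 rose by 0.72 (adjusted p = 3.74e-08) and Ucp1, below 1 CPM, by 2.23 (adjusted p = 0.00832). Cholesterol synthesis had 20 of 24 genes higher (median 0.55, adjusted p = 2.24e-20; adjusted p = 0.0486 with an estimated correlation) and de novo lipogenesis 13 of 18 (14 adjusted over the list alone; median 0.6, adjusted p = 1.7e-17; adjusted p = 0.0276 with an estimated correlation).

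In KO mice, genes of lipid synthesis were again lower on omega-6 than on saturated fat. Acsl3, which activates fatty acids on lipid droplets, and Tlcd2, a membrane lipid regulator, fell with Podnl1, and Mt2 and Alkal2 rose. Here 3474 genes changed (1361 higher, 2113 lower), against 1736 without the libraries high in B cell or muscle markers, 1960 with 3 cell-type lists as covariates and 2055 without replicate 3 of KO on SFA. Podnl1 fell from 27.5 ± 9.71 to 4.93 ± 0.547 CPM (-2.48, adjusted p = 2.48e-07), Tlcd2 from 73.4 ± 14.4 to 17.6 ± 1.63 CPM (-2.06, adjusted p = 7.88e-10) and Acsl3 from 121 ± 10.9 to 49.1 ± 2.17 CPM (-1.29, adjusted p = 7.88e-10). Rasd1 (-1.35), Il20rb (-1.3) and Nabp1 (-1.22, adjusted p = 0.000177) fell, and Slc15a2 (1.37), Alkal2 (1.36, adjusted p = 5.43e-05), Cux2 (1.31), Sez6l (1.14) and Mt2 (1.09) rose. Cholesterol synthesis had 23 of 24 genes lower (24 adjusted over the list alone; median -0.58, adjusted p = 5.26e-26; adjusted p = 0.0247 with an estimated correlation), among them Idi1 (-0.85), and de novo lipogenesis 14 of 18 (median -0.54, adjusted p = 8.9e-16; adjusted p = 0.0247 with an estimated correlation), among them Acly (-0.85). Macrophage markers had 9 of 15 higher (10 adjusted over the list alone; median 0.33, adjusted p = 2.24e-05; adjusted p = 0.462 with an estimated correlation), with Cd163 at 0.69, and 2 called without the libraries high in B cell or muscle markers (median 0.27). WT and KO shared 546 genes higher and 1063 lower on n6 against SFA, where 158.5 and 276.8 were expected, with 17 opposite. On n3 against n6 they shared 689 higher (236.3 expected) and 194 lower (134.9 expected), with 92 opposite, and on n3 against SFA 0 higher and 2 lower (0.1 and 0.1 expected). In TPM units 3319 genes were higher and 501 lower, with the median of all genes shifted by 0.112.

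Omega-3 against saturated fat in KO mice gave few called genes. Acsl3, which activates fatty acids, and Tlcd2 fell, and Fmod, a matrix proteoglycan, and Mmp9, which cleaves matrix, rose. The 223 called genes (126 higher, 97 lower) became 81 without replicate 1 and 866 without replicate 4 of KO on n3. They became 587 by DESeq2 and 31 when only the groups compared were fitted. Leaving out the 100 most abundant genes gave 99 higher and 118 lower. Podnl1 (-1.34, adjusted p = 0.00194), Tlcd2 (-1.24, adjusted p = 6.21e-06) and Acsl3 (-0.75, adjusted p = 1.04e-05) fell. Gnal (1.35, adjusted p = 0.00398), Mmp9 (0.99, adjusted p = 0.0123), Sfrp5 (0.79, adjusted p = 0.0061), Dusp15 (0.74) and Fmod (0.71, adjusted p = 0.000587) rose. Lpcat3 was lower on n3 (-0.37, adjusted p = 0.00224). Cholesterol synthesis had 9 of 24 genes lower (15 adjusted over the list alone; median -0.25, adjusted p = 6.15e-19; adjusted p = 0.097 with an estimated correlation), with Fdps at -0.46, and de novo lipogenesis 7 of 18 (10 adjusted over the list alone; median -0.2, adjusted p = 1.05e-10; adjusted p = 0.109 with an estimated correlation), with Scd2 at -0.51.

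Between omega-3 and omega-6 fat in KO mice, cholesterol synthesis genes were higher on omega-3. Fewer of them were called in the settings given below, while their median was clearly smaller only in TPM units. Podnl1, Rasd1 and Tlcd2 rose, and Mal and Drp2, known from myelinating cells of nerves, fell. Here 3972 genes changed (2405 higher, 1567 lower), against 1407 without the libraries high in B cell or muscle markers, 280 with 3 cell-type lists as covariates and 2051 without replicate 3 of KO on n3. Podnl1 (1.13, adjusted p = 0.00212), Rasd1 (1), Tlcd2 (0.83, adjusted p = 0.000705) and Bhlhe41 (0.68) rose, and Pygm (-1.21), Mal (-0.97) and Plekhg1 (-0.89) fell. Cholesterol synthesis had 20 of 24 genes higher (22 adjusted over the list alone, median 0.34, and adjusted p = 0.318 with an estimated correlation). The count was 11 in TPM units (median 0.18) and 10 with 3 cell-type lists as covariates (median 0.38). Without the libraries high in B cell or muscle markers it was 15 (median 0.33). Oxidative phosphorylation had all 43 (median 0.24; adjusted p = 0.41 with an estimated correlation) against 15 in TPM units (median 0.08) and 1 called with 3 cell-type lists as covariates (median 0.19), and ribosomal proteins had 23 of 26 (25 adjusted over the list alone; median 0.19; adjusted p = 0.41 with an estimated correlation) against 6 in TPM units. Endothelial markers had 12 of 14 lower (13 adjusted over the list alone; median -0.52, adjusted p = 5.69e-11; adjusted p = 0.41 with an estimated correlation), against 1 called with 3 cell-type lists as covariates (median -0.41) and 8 without the libraries high in B cell or muscle markers (median -0.5), and skeletal muscle markers 10 of 16 (13 adjusted over the list alone; median -2.79, adjusted p = 0.0102; adjusted p = 0.616 with an estimated correlation), where 0 were called without those libraries (median -0.44). TPM units gave 328 higher and 3073 lower genes, with the median of all genes shifted by -0.0987, and leaving out the 100 most abundant genes gave 1792 higher and 1884 lower.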

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

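The tests on patterns in this part were chosen after the results were seen, apart from the splits of the libraries, which were set before the data were examined.

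For most gene counts no other split of the libraries reached the real count. A share of 1 of 35 is the smallest that 35 splits can give, and it was not adjusted over the comparisons. It is therefore weak evidence against chance for any single count. Only the real split reached the real count (1 of 35) for KO against WT on SFA (6086 genes, highest other split 17), n6 (6571, highest other 738) and n3 (5924, highest other 3211), and 1 of 60 did for the average (8795, highest other 1326). In WT the same held for n6 against SFA (3776, highest other 1291), n3 against SFA (22, highest other 0) and n3 against n6 (2813, highest other 225), and in KO for n6 against SFA (3474, highest other 904) and n3 against n6 (3972, highest other 2753). For n3 against SFA in KO, 3 of 35 splits reached the real 223 genes and another gave 988, so chance cannot be excluded and the libraries hold a structure other than diet. For the interaction, 2 of 60 splits reached the real 983 genes (highest other 2150), but these splits shuffle diet labels within genotype and so break the diet effects too, and whether chance can be excluded stays open.

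These splits can neither exclude chance for the number of lists called nor show it. Many of the 35 exchange a single library between the groups and so keep part of the real difference. On SFA, n6 and n3, 7, 9 and 8 of 35 splits of KO and WT reached the real 23, 26 and 26 lists, with highest others of 31, 32 and 29. In WT, 5, 10 and 5 of 35 splits reached the real 27, 13 and 24 lists for n6 against SFA, n3 against SFA and n3 against n6 (highest others 27, 26 and 27). In KO, 7, 11 and 4 of 35 reached the real 27, 18 and 26 (highest others 33, 27 and 30). For the average over diets 2 of 60 splits reached the real 28 (highest other 28). With an estimated correlation 0 lists were called for this average, so chance was not excluded there either.

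A first pattern is a set of processed pseudogenes, silent copies of other genes, that rose in KO on every diet far more than their parent genes. Gm11868, a copy of Cyb5r4, was at 10.7%, 10.3% and 11.4% of its parent in KO and 0, 0 and 0.0111% in WT on SFA, n6 and n3; Gm7049 (copy of Me1), Morf4l1-ps1 (Morf4l1) and Gm3953 (Nsa2) were the others, all named after their values were seen. Reads shared with a parent gene that rose were not tested apart from this choice. The pseudogenes were picked by their rise over the parent (smallest difference 2.12 log2). On SFA, n6 and n3, the parents Cyb5r4 (-0.25, -0.46 and -0.24) and Morf4l1 (-0.34, -0.35 and -0.26) were themselves lower in KO. The parent Me1 was higher (1.47, 1.76 and 1.18), and Nsa2 was at 0.11, 0.04 and 0.1. A chromosome 9 segment of another strain in the KO libraries stays open: 3 of the 4 parents lie within 3.53 Mb on chromosome 9 (permutation p = 0.013 for sharing a chromosome, which missed its bound, and 0.003 for lying close, a test added after the first missed), and near the segment 26.1% of 46 genes, against 17.4% of all genes, had no overlap between KO and WT within each diet (Fisher exact p = 0.121), which settles nothing. No biological explanation was tested.

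The next pattern is the rise of lipogenic and cholesterol genes in KO on all 3 diets. A few abundant genes taking the counts were not tested by leaving out the 100 most abundant genes (92.1% of the members left stayed called higher, 35 of 38), which hardly changes the scaling. Those 100 genes held a larger share of the counts in KO than in WT (36.5% against 31.9% on SFA, 33.4% against 27.6% on n6 and 35.2% against 30% on n3). Unscaled, this lowers the share of the other genes in KO. The mean TMM factors were lower in KO (0.923 against 1.01, 0.996 against 1.1 and 0.934 against 1.05), which raises the scaled values of KO. Averaged over diets, the medians were 0.64 for cholesterol synthesis and 1.08 for de novo lipogenesis in TPM units, against 0.89 and 1.32. A larger share of adipocytes in the KO samples does not account for the whole rise. The median log2 fold change of 24 mature adipocyte genes outside these lists was 0.22, against 0.98 for the lipogenic genes (difference 0.75, permutation p = 0.00071). That permutation moved genes between the lists, so its p does not measure the spread between libraries. A smaller part of the rise from cell shares was not excluded. A response of the tissue to the LPCAT3 genotype remains a candidate explanation, and these data hold no test of its mechanism.

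The last pattern is in the endothelial markers, of which 11 of 14 were called higher in KO on SFA and 6 lower on n3; of the SFA rises 0 were called in TPM units and 1 without the libraries high in B cell or muscle markers, while 13 were lower on n3 in TPM units (median -0.5). The genotype effect on the endothelial list differed between these diets by -0.6 log2 (SE 0.15). Glandular epithelium in some libraries does not account for the endothelial difference, which was -0.55 (SE 0.17) with gland markers as a covariate. Lymphoid tissue in some libraries was not decided, although the difference was -0.6 (SE 0.16) with B cell markers as a covariate. Mean B cell markers differed little between KO and WT (0.75 against 0.91 log2 CPM on SFA, 0.35 against 0.4 on n3). That covariate could therefore hardly move the difference. Endothelial markers were at 6.26, 6.25, 6.16 and 6.67 mean log2 CPM in replicates 1 to 4 of KO on n3, against 6.51, 6.26, 6.29 and 6.17 in WT on SFA and 6.35 in replicate 2 of WT on n3, so uneven sampling of vessels was not excluded, nor separated from a diet-dependent effect of LPCAT3.

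Single libraries stood far from the other 3 of their group in 27 of 354 sets of 4, where chance gives about 17.7 (1 in 20). Among list means (log2 CPM) these were cholesterol synthesis in KO on SFA 1 (6.49) and WT on n3 4 (5.33), polyunsaturated fatty acid synthesis in WT on SFA 1 (6.46), mitochondrially encoded genes in KO on SFA 3 (10.72), cell cycle in WT on SFA 3 (3.02) and KO on n6 1 (2.87), inflammatory cytokines in KO on n3 3 (1.48), matrix in KO on SFA 3 (7.76), T and NK cell in WT on n6 4 (0.26) and WT on n3 4 (1.16), skeletal muscle in WT on SFA 1 (0.36) and ribosomal proteins in KO on SFA 2 (7.31). Among genes (CPM) they were Nabp1 in KO on n3 3 (563), Saa3 in KO on SFA 1 (1.69), WT on n6 4 (24.1) and WT on n3 2 (18.4), Nnat in KO on SFA 4 (133), Cfd in KO on n6 3 (179) and WT on n3 2 (847), and Cyp2f2 in KO on SFA 4 (1.56) and KO on n6 3 (1.29). Itgad in KO on SFA 1 (15.2), Folh1 in KO on n3 3 (5.46), Cidea in WT on n6 4 (7.78), Gm11868 in WT on n3 3 (0.0152) and Krt8 in KO on n6 2 (1.04) and WT on n3 3 (0.0152) completed them.

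The genotype effect differed between diets, by the edgeR interaction test, for 983 genes. Among genes of the text the adjusted p was 0.00696 for Lpcat3, 0.0191 for Prune2, 0.0326 for Hebp2, 0.0115 for Saa3, 0.0453 for Cfd, 0.0108 for Folh1, 0.00178 for Scd1, 2.61e-05 for Acss2, 0.000501 for Insig1, 0.000118 for Ighm, 0.0231 for Fdps, 0.0366 for Acly, 0.00326 for Acacb, 0.00751 for Cidea, 0.00834 for mt-Nd2 and 0.0207 for Hba-a2.

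The genotype effect differed between diets by camera for 21, 17 and 15 lists for n6 minus SFA, n3 minus SFA and n3 minus n6, and for 0, 0 and 0 with an estimated correlation. Each list of the text is given once, at the pair of diets with its smallest p, with the median over its genes of the difference in log2 fold change. For n6 minus SFA these included triglyceride synthesis (0.1), beta-oxidation (0.22), thermogenic (0.18), tricarboxylic acid cycle (0.17), mitochondrially encoded (0.33), cell cycle (-0.37), B cell (2.63), T and NK cell (1.03), mature adipocyte (0.1) and lipolysis (0.17). The B cell value depends on the libraries high in these markers. KO against WT medians were 0.37 on SFA and 0.86 on n6 without the libraries high in B cell or muscle markers, against -0.2 and 2.23 with all. The medians of 0.3 and 0.03 with 3 cell-type lists as covariates test nothing here, since the B cell list is among those covariates. For n3 minus SFA they included cholesterol synthesis (-0.2), oxidative phosphorylation (0.17), MHC class II (0.32), matrix (0.22), endothelial (-0.63), pericyte (-0.46), gland (1.56), adipokines (0.22) and ribosomal proteins (0.18). For n3 minus n6 they included de novo lipogenesis (-0.27), interferon response (-0.46) and erythroid (-0.57).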

How the results depend on the processing

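Of 8795 genes called in the average over diets, 8617 kept their call and direction with RLE scaling, 8644 with DESeq2 and 5856 in TPM units. The share of called genes that were higher was 48.3% in the main fit and 13.1% in TPM units. Apart from Lpcat3 and Ucp1, the named genes were picked by their calls in the main fit. Their values therefore cannot show how far results held across all genes. Among the named genes, 10092 of 10424 values under the alternatives kept their direction and their side of the threshold. Of the rest, 293 lost their call, 27 gained one and 12 turned their sign. Refits with 1 library left out gave 4920 of the 10424 values. The sign turned for Lpcat3 in TPM units, with pseudocounts of 1 or 0.1 or with no filter, for KO against WT on SFA (0.07) and n6 (0.10) and for n3 against SFA in WT (0.03). The last was also 0.02 without the libraries high in B cell or muscle markers and ranged from -0.11 to 0.02 with each library left out, the highest without replicate 3 of WT on SFA. Ucp1 for KO against WT on n3 ranged from -0.3 to 0.07, the highest without replicate 4 of WT on n3. The causes of the changes in this part were not tested, apart from the smaller number of libraries in some settings. RLE scaling left 468 of 469 named values as they were, and DESeq2 460 of 468. Depth differed between groups, with mean totals from 46.1 M in KO on n6 to 55.3 M in KO on SFA, so low-count genes such as Ucp1 are measured least well.

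Counts of called genes moved by over 1.5 times in these settings. With B cell, muscle and gland lists as covariates, chosen after seeing the data, they were 3797 for KO against WT on n3, 1960 for n6 against SFA in KO, 124 for n3 against SFA in KO, 280 for n3 against n6 in KO and 87 for the interaction. The gland list did not overlap between KO and WT on n3, so the 3797 cannot tell cell shares from genotype. Without the libraries high in B cell or muscle markers, also chosen after seeing the data, the counts were 1736 for n6 against SFA in KO, 1407 for n3 against n6 in KO and 318 for the interaction. DESeq2 gave 339 for n3 against SFA in WT, 587 for n3 against SFA in KO and 1975 for the interaction. TPM units gave 6166 (pseudocount 1) and 5991 (0.1) for n6 against SFA in WT and, with no filter, 8 for n3 against SFA in WT and 590 for the interaction. Fitting only the groups compared gave 31 for n3 against SFA in KO and 1724 for n3 against n6 in KO. A block for replicate number gave 44 for n3 against SFA in WT and 504 for the interaction, and the B cell list as covariate 532 for the interaction.

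With an estimated correlation, 3, 2, 2 and 0 lists were called for KO against WT on SFA, n6, n3 and averaged, in place of 23, 26, 26 and 28. In WT the calls were 3, 0 and 3 for n6 against SFA, n3 against SFA and n3 against n6 (27, 13 and 24 with the preset), in KO 3, 0 and 0 (27, 18 and 26), and for the differences of genotype effects 0, 0 and 0 (21, 17 and 15). The n3 minus n6 difference had 25 lists with the 3 list covariates.

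Leaving out each library in turn gave 5283 to 5943 called genes for KO against WT on SFA, 5767 to 6519 on n6, 4764 to 6629 on n3 and 8502 to 8967 averaged. In WT the ranges were 2393 to 4232 for n6 against SFA, 1 to 111 for n3 against SFA and 1980 to 3182 for n3 against n6. In KO they were 2055 to 4188, 81 to 866 and 2051 to 5291, and for the interaction 515 to 2527. Lists ranged from 23 to 24, 25 to 30, 24 to 27 and 26 to 28 for KO against WT, from 27 to 28, 8 to 22 and 19 to 25 in WT, from 24 to 31, 17 to 20 and 24 to 28 in KO, and from 20 to 23, 14 to 23 and 12 to 20 for the differences of genotype effects.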

Other observations

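The tests of the hypothesis in this part were chosen after the results were seen. Lipolysis genes, which free stored fat, had 6, 10 and 7 of 14 higher and 1, 0 and 0 lower in KO on SFA, n6 and n3 (7, 11 and 8 higher and 1, 0 and 0 lower adjusted over the list alone), with medians of 0.19, 0.38 and 0.27 (camera adjusted p = 0.0159, 2.45e-05 and 0.000348; adjusted p = 0.446, 0.232 and 0.259 with an estimated correlation). In TPM units the counts were 3, 7 and 5 higher and 2, 2 and 2 lower, with medians of 0.01, 0.15 and 0.02. Prkaca, a subunit of the kinase that starts lipolysis, rose by 0.77 on SFA (adjusted p = 5.78e-11), 0.76 on n6 and 0.65 on n3, Abhd5 by 0.67, 0.63 and 0.63, and the beta-adrenergic receptor Adrb3 by 0.59, 1.24 and 0.8. Mature adipocyte genes had 13, 13 and 14 of 24 higher and 5, 3 and 3 lower (13, 14 and 15 higher and 6, 3 and 3 lower adjusted over the list alone), and were called on n6 (median 0.21, adjusted p = 0.00147; adjusted p = 0.456 with an estimated correlation) and n3 (0.27, adjusted p = 0.000356; adjusted p = 0.488 with an estimated correlation). In TPM units 8, 10 and 11 were higher and 8, 8 and 6 lower, with medians of 0.02, 0.06 and 0.04. Nat8l rose by 1.77 on n6, and Lep fell on SFA, at -0.68.

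Cytokines and chemokines, which recruit immune cells, had 7, 7 and 9 of 19 lower in KO and none higher, and were called on SFA (median -0.35, adjusted p = 0.0165; adjusted p = 0.441 with an estimated correlation) and n3 (-0.42, adjusted p = 0.00165; adjusted p = 0.279 with an estimated correlation). Ccl2, which attracts monocytes, fell on SFA, n6 and n3, at -1.08 (adjusted p = 8.49e-07), -1.7 (adjusted p = 4.64e-10) and -1.07. Interferon response genes had 6, 15 and 2 of 23 higher and none lower (5 and 18 higher on SFA and n6 adjusted over the list alone), and were called on n6 (median 0.41, adjusted p = 7.7e-05; adjusted p = 0.456 with an estimated correlation), with Cxcl9 at 1.55 (adjusted p = 8.39e-08) and Ifit3 at 0.86. In TPM units 3, 5 and 1 were higher and 3, 0 and 7 lower (n3 median -0.21), and 6 were higher on n6 without the 4 libraries high in B cell or muscle markers. Ighm, the heavy chain of IgM, was at 582.2 ± 41.8 CPM in WT and 101.8 ± 11 in KO on SFA, 674.5 ± 14 and 350.4 ± 46 on n6, and 615.2 ± 53.2 and 265.9 ± 61.6 on n3 (mean ± SD, n = 4).

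A hypothesis was tested that the KO genotype and the n6 diet move the same genes in opposite directions. KO against WT on n3 was set against n6 against SFA in WT, which share no library. Pearson's r across genes was -0.25, which missed its bound of -0.3, with a Spearman correlation of -0.53, so the hypothesis stays open. A second look was added after the first had missed. Of the 2522 genes called in both comparisons, 97.4% moved in opposite directions, where 50.1% were expected from independent calls. Of these 2522, 1442 were higher in KO and lower on n6 (401.5 expected), 1014 the reverse (332.9 expected), and 66 moved the same way (731.5 expected). Genes that move together can push such a share far from 50.1% in either direction, so it does not decide the question.

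Near genes of the text, some neighbours differed in KO on every diet and were picked after their values were seen. Rfc4 (0.73, 0.73 and 0.71 on SFA, n6 and n3) and Eif4a2 (0.37, 0.61 and 0.44), next to Adipoq on chromosome 16, were higher in KO, while Adipoq was lower (-0.57, -0.24 and -0.25). Tbx18 on chromosome 9, near the parents of the pseudogenes, was at -0.78, -0.44 and -0.88.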
